A study of Mus musculus with 8 samples.

How the data were processed

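Hematopoietic stem cells were sorted from mouse bone marrow as KSL SLAM cells, which the labels define by the absence of lineage markers, CD48 and CD41 and the presence of c-Kit, Sca-1 and CD150. The mice had received granulocyte colony-stimulating factor (G-CSF), the cytokine that drives neutrophil production and releases stem cells into blood, at 125 mcg per kg 2 times a day under the skin, or phosphate-buffered saline (PBS), for 36 h. Each of the 8 samples held cells from 5 to 10 mice, and the labels describe 4 independent PBS and 4 independent G-CSF samples. RNA was purified on RNA XS columns, amplified with NuGen Ovation, labelled with biotin and hybridized to MoGene 1.0 ST arrays, per the labels' protocols.

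The deposited values are 1 intensity per probe set and array on a linear scale, and RMA is the tool named in the submitters' processing notes. The RMA software, its version, and the background and normalization options are not given in the sources used here. RMA ordinarily returns log2 values. The deposited intensities ran from 2.15 to 16162 and were never negative, so they were read as RMA values returned to the linear scale, and log2 was taken before each test. The median intensity of all probe sets was between 47.0 and 54.8 on each array. Scanner files were not used here, so no detection call or hybridization date was available to the tests. The number of arrays limits the precision.

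Of 35556 probe sets, 21789 carried 1 gene symbol in the platform annotation, 1621 carried several and 12146 carried none. Identifiers of 21698 of the single-gene probe sets were found in a RefSeq gene table (GRCm38.p6, used for names only), and 0 symbols changed. Probe sets with several symbols or none were left out of the gene tests. For the 999 genes with more than 1 probe set, the probe set with the highest mean over all arrays was kept, which left 19938 genes. Ly6a, the gene of Sca-1, had no probe set of its own under these rules and was not analysed here.

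G-CSF and PBS samples were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust options, 2-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. No filter on dim genes was applied. Each of 28 gene lists was tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the 28 lists. Camera with an estimated correlation and fry were run beside it. Camera asks whether a list ranks differently from the other genes, whereas fry asks whether the list's genes move on balance one way. Means of a list's log2 values per array were compared by an exact 2-sided permutation test, whose smallest possible p with 4 against 4 arrays is 0.0286. As a description, each list's median log2 fold change was ranked among 10000 random lists of genes of like mean intensity. The random genes were drawn independently, so these percentiles take no account of correlation among a list's members. The lists cover pathways, signs of RNA quality and handling, and markers of other cell types. The Toll-like receptor list was included because a publication on these mice is known to concern that pathway.

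The tests, lists and rule for named genes were fixed before the data were examined. The rule names the 12 highest and 12 lowest fold changes among genes past the threshold whose 4 values in each group did not overlap. Predicted genes, accession-like names, receptor and immunoglobulin segments, snoRNAs, microRNAs and histones were left out of it. Where fewer than 5 genes passed in a direction, it names the 5 with the lowest p and says that they did not pass. It further allows up to 4 members of each list with the lowest p, and always names Csf3r, Socs3, Cxcr4, Kit, Ly6a, Slamf1, Cd48, Itga2b, Tlr2, Tlr4, Myd88, Mki67 and Cdkn1c.

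The scripts were tested on simulated arrays with the means and spreads of the 19938 genes in the comparison of 4 G-CSF with 4 PBS arrays. Of the genes changed by 1 on the log2 scale, 44 of 67 were recovered. Of those changed by 2, 67 of 67 were recovered, and of those changed by 3, 66 of 66. The 189 calls further held 10 false calls and 2 members of a planted list of 30 genes. The planted list was found and 0 of 27 unchanged lists were called. The genes were simulated independently, so this does not test the list calls where members are correlated. The estimated correlation of the neutrophil markers, for example, was 0.59. The simulated spreads were those after limma's moderation, and 189 calls allowed a more lenient cut-off than the 19 of the real comparison. The recovery therefore does not carry over to every gene. In the real comparison the neutrophil marker Stfa2, with a log2 fold change of 4.56 ± 0.76 SE, did not pass (limma adjusted p = 0.0639).

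The alternatives were another moderation of the variances, the replicate number as a block, array weights, a filter on dim genes, renewed quantile normalization, median centring, other choices of probe sets, other thresholds, other list tests, and leaving out each array in turn. Quantile normalization with PBS replicate 3 left out, and a neutrophil marker score as a covariate, were added after the data had been seen.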

Results

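Expression was measured in sorted bone marrow hematopoietic stem cells from mice given G-CSF or PBS for 36 h, with 4 arrays per group and cells pooled from 5 to 10 mice per array. The comparison asks which transcripts differ in stem cells after G-CSF. The medians of the 19938 genes were alike, between 5.74 and 5.89 on the log2 scale. PBS replicate 3 stood apart from the other arrays. Its interquartile range was 1.68, against 2.41 to 2.80 in the others, and its correlation with them was 0.883 to 0.903, whereas the other arrays correlated with each other at 0.956 to 0.977. It was kept in the main comparison as designed.

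**Figure D1:**
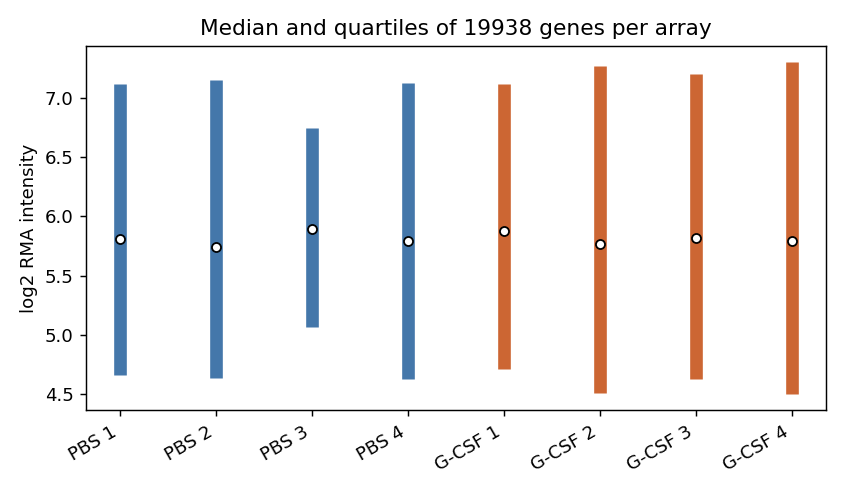
Log2 intensity of 19938 genes on each of the 8 arrays (horizontal axis), with the median as a circle and the range between the quartiles as a bar, PBS in blue and G-CSF in orange. PBS replicate 3 has the narrowest bar, with quartiles at 5.07 and 6.75.

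After G-CSF, 19 genes were higher and 0 were lower at an adjusted p under 0.05 (limma). The 4 G-CSF values of each of the 19 genes lay above all 4 PBS values. They included Socs3, the feedback inhibitor of cytokine receptor signalling, which was 2.57-fold higher (log2 fold change 1.36 ± 0.18 SE, adjusted p = 0.0198), and Csf2rb, the common beta chain of the receptors for GM-CSF, IL-3 and IL-5, which was 3.01-fold higher (1.59 ± 0.21 SE, adjusted p = 0.0198). At an unadjusted p under 0.05, 1211 genes were higher and 586 lower, where 997 genes in all are expected by chance. The groups did not overlap at 6.15% of genes, against 2.86% by chance.

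The largest change was that of Wfdc17, a secreted protein with a WAP domain, with a mean log2 intensity of 11.19 ± 0.29 (SD, n = 4) after G-CSF and 5.85 ± 1.68 (SD, n = 4) after PBS, a log2 fold change of 5.33 ± 0.65 SE. Its relative Wfdc18 rose by 1.96 ± 0.26 SE. Tgfbi, an extracellular matrix protein induced by TGF-beta, had the lowest adjusted p of 0.00721 and was 6.82-fold higher. Vldlr, the very low density lipoprotein receptor, was 7.14-fold higher, and Lipg, endothelial lipase, 7.12-fold higher. Lrg1, a secreted leucine-rich glycoprotein, was 9.74-fold higher. Without PBS replicate 3 Lrg1 and Lipg did not pass (adjusted p = 0.103 and 0.0904), with log2 fold changes of 3.25 and 2.86, against 3.28 and 2.83 with all arrays. The C-type lectin Clec4e rose by a log2 fold change of 1.72 and the interleukin-10 receptor chain Il10ra by 1.94. Ceacam10, of the carcinoembryonic antigen family, rose by 2.42 ± 0.25 SE. Serpinb1a, an inhibitor of neutrophil serine proteases, rose by 2.25 ± 0.31 SE and the kinetochore gene Cenph by 2.15 ± 0.28 SE. The spread among the G-CSF arrays was wide for Lrg1 (SD 1.05) and Lipg (SD 1.03) and narrow for Clec4e (SD 0.12) and Csf2rb (SD 0.15).

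**Figure D2:**
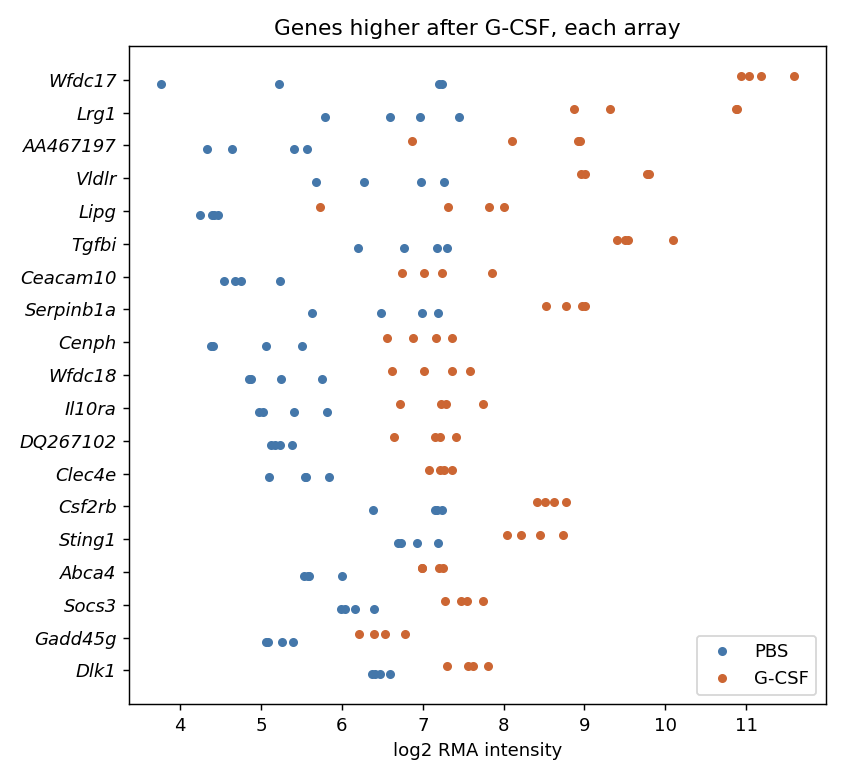
Log2 intensity (horizontal axis) of the 19 genes higher after G-CSF, 1 point per array, with PBS in blue and G-CSF in orange. For every gene the 4 G-CSF points lie above the 4 PBS points, and the gap between the group means is widest for Wfdc17, at 5.33.

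The count depended on which probe sets entered the fit. With all 35556 probe sets, 0 passed the threshold, the lowest adjusted p being 0.0615, with 2743 at an unadjusted p under 0.05. Without G-CSF replicate 2 the count was 3 (Ceacam10, Tgfbi and the accession-like DQ267102, the last named after its value was seen), without G-CSF replicate 4 it was 7 and without G-CSF replicate 1 it was 10. It was 31 without G-CSF replicate 3. After renewed quantile normalization 7 genes passed. Of 17 alternatives with an adjusted p for each named gene, Lrg1 and Sting1 did not pass in 10 and Gadd45g in 9, Lipg did not pass in 11 of 16, and the other 11 named genes did not pass in 1 to 6.

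No gene named by the rule was lower at the threshold. The 5 with the lowest p did not pass. They were the cation channel Trpc6 with a log2 fold change of -1.27 (adjusted p = 0.104, with 0.047 with array weights and 0.0472 without PBS replicate 1), Tex38 with -0.83, the reduced folate carrier Slc19a1 with -1.31 (adjusted p = 0.193), the circadian gene Per2 with -0.70 and the nuclear receptor Nr4a2 with -0.79. Without PBS replicate 3, Slc19a1 was lower by a log2 fold change of -1.63 ± 0.13 SE (adjusted p = 0.0064, against 0.00342 to 0.998 over 17 alternatives), and the small nucleolar RNA Snora20, chosen after its value was seen, was the other of the 2 lower genes.

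Genes of STAT3 and STAT5 signalling, which lies downstream of the G-CSF receptor, ranked above the other genes (camera adjusted p = 7.23e-11, median log2 fold change 0.42). The adjusted p = 0.0769 with an estimated correlation, and by fry it was 0.0129. The median was 0.24 after quantile normalization, with or without PBS replicate 3. Of the 32 members, 3 rose over all genes, namely Socs3, Gadd45g and Lrg1, and 8 when adjusted over the list alone. The remaining 24 did not pass. Csf3r, which encodes the G-CSF receptor, had a log2 fold change of 1.29 ± 0.21 SE (adjusted p = 0.0585), and 1.46 without PBS replicate 3 (adjusted p = 0.0125, against 0.00387 to 0.88 over 17 alternatives).

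Granulocyte-monocyte progenitor genes ranked above the others with the preset correlation (camera adjusted p = 3.93e-14) and with an estimated correlation (adjusted p = 0.0186). By fry, which tests the list against no change, the adjusted p was 0.00686. Their median log2 fold change was 0.95, and 0.57 with the neutrophil marker score of each array as a covariate. Of 24 members, 2 rose over all genes, Csf2rb and Sting1, the adaptor of cytosolic DNA sensing, and 12 when adjusted over the list alone. Prtn3, the granule protease proteinase 3, had a log2 fold change of 1.38 ± 0.24 SE (adjusted p = 0.068).

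Neutrophil markers had the highest median log2 fold change of the 28 lists, 1.60 (camera adjusted p = 2.03e-22). The list's adjusted p = 0.104 with an estimated correlation, and by fry it was 0.0915. None of the 24 members passed over all genes, and 21 rose when adjusted over the list alone. Stfa2, a stefin of granulocytes, had a mean log2 intensity of 8.13 ± 2.03 (SD, n = 4) after G-CSF and 3.57 ± 0.17 (SD, n = 4) after PBS. The chemokine receptor Cxcr2 had a log2 fold change of 3.35 ± 0.72 SE, lactoferrin (Ltf) 2.33 ± 0.43 SE and Anxa1 2.14 ± 0.34 SE. The mean of the markers was 9.58, 9.64, 7.83 and 8.33 in G-CSF replicates 1 to 4, against 6.92 to 7.64 in the PBS arrays. Monocyte and macrophage markers had a median of 0.24 (camera adjusted p = 0.004). Their adjusted p = 0.486 with an estimated correlation, and 0 of 26 passed when adjusted over the list alone. The camera call ended without PBS replicate 3 (adjusted p = 0.0543, median 0.07), without G-CSF replicate 2 (adjusted p = 0.0901, median 0.09), with array weights (adjusted p = 0.054, median 0.07), after quantile normalization (adjusted p = 0.0626, median 0.16), in the 9969 brighter genes (adjusted p = 0.4, median 0.24) and with quantile normalization and PBS replicate 3 left out (adjusted p = 0.152, median -0.01). Without PBS replicate 1 the median was 0.38 (adjusted p = 1.29e-06). With the neutrophil covariate, the monocyte and macrophage list ranked below the other genes (adjusted p = 0.000485, median -0.43).

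**Figure D3:**
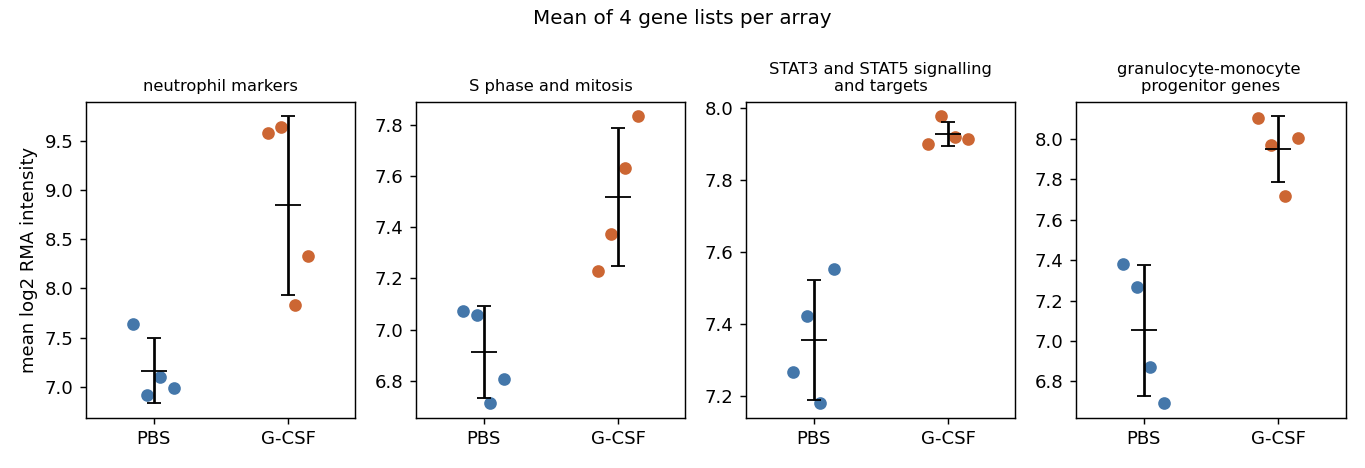
Mean log2 intensity of 4 gene lists (vertical axis, a scale per list) on each array, PBS in blue and G-CSF in orange, with the mean and SD of 4 arrays in black. The neutrophil markers have an SD of 0.909 over the G-CSF arrays and the STAT3 and STAT5 list has 0.0338.

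All 48 measured genes of S phase and mitosis had a positive log2 fold change, with a median of 0.61 (camera adjusted p = 6.62e-21). Their adjusted p = 0.104 with an estimated correlation, and by fry it was 0.0882. None passed over all genes, and 19 rose when adjusted over the list alone. Cyclin B2 (Ccnb2) had a log2 fold change of 1.15 ± 0.29 SE, the spindle factor Tpx2 1.03 ± 0.25 SE, and the proliferation marker Mki67 0.71 ± 0.18 SE (adjusted p = 0.292). Genes of quiescence and cell cycle restraint did not rank apart (camera adjusted p = 0.675, median 0.06), but ranked lower with quantile normalization and PBS replicate 3 left out (adjusted p = 0.0496). Cdkn1c, an inhibitor of cyclin-dependent kinases, had a log2 fold change of -0.27 ± 0.22 SE. The S phase and mitosis mean was 7.23, 7.37, 7.63 and 7.83 in G-CSF replicates 1 to 4, where the neutrophil marker mean was 9.58, 9.64, 7.83 and 8.33.

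The Toll-like receptor pathway ranked above the other genes (camera adjusted p = 0.000349, median log2 fold change 0.20). The pathway's adjusted p = 0.125 with an estimated correlation, and by fry it was 0.122. The camera call ended in the 9969 brighter genes (adjusted p = 0.152, median 0.26) and with the neutrophil marker score as a covariate (adjusted p = 0.593, median 0.09). The median was 0.13 after quantile normalization and 0.30 without PBS replicate 1. None of the 35 members passed over all genes or when adjusted over the list alone. The array means overlapped, with 6.514 and 6.504 in PBS replicates 1 and 4 and 6.496 in G-CSF replicate 3 (exact permutation p = 0.0857). The adaptor Myd88 had a log2 fold change of 0.95 ± 0.37 SE (adjusted p = 0.507), the receptors Tlr2 and Tlr4 had 0.40 ± 0.24 SE and 0.49 ± 0.30 SE, and Ly96, the partner of Tlr4 at the cell surface, had 1.50 ± 0.58 SE. Without PBS replicate 3 Myd88 had 0.59 and Tlr4 0.19, whereas Tlr2 had 0.58 and Ly96 2.03. Genes of NF-kB targets and inflammatory mediators had a median of 0.11 (camera adjusted p = 0.00525). Their adjusted p = 0.104 with an estimated correlation, and their median lay at percentile 72.36 among random lists of like intensity. The camera adjusted p was 0.0588 without PBS replicate 3 (median 0.07), 0.0766 after quantile normalization (median 0.07), 0.177 with both (median 0.07), 0.438 in the brighter genes (median 0.25) and 0.213 with the neutrophil covariate (median 0.04). The median was 0.05 with array weights and 0.17 without PBS replicate 1. When adjusted over the list alone, 3 of 31 rose, and Bcl3, a nuclear partner of NF-kB, had 1.70 ± 0.34 SE. Interferon-stimulated genes did not rank apart (camera adjusted p = 0.178, median 0.05), although they ranked higher without PBS replicate 4 (adjusted p = 0.0145), without G-CSF replicate 1 (adjusted p = 0.0209) and with the neutrophil covariate (adjusted p = 7.9e-06). Their median was -0.06 without PBS replicate 3. Ifitm1 had 1.05 ± 0.20 SE (adjusted p = 0.118).

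Metabolic lists ranked above the other genes. Oxidative phosphorylation had a median log2 fold change of 0.39 (camera adjusted p = 2.56e-11, and with an estimated correlation adjusted p = 0.125) with 39 of its 40 members positive and 1 higher when adjusted over the list alone. Glycolysis and hypoxia had 0.36 (camera adjusted p = 3.91e-06, and with an estimated correlation adjusted p = 0.104), with 4 of 32 higher when adjusted over the list alone, and antioxidant genes had 0.26 (camera adjusted p = 3.55e-05, and with an estimated correlation adjusted p = 0.151), with 1 of 27 higher when adjusted over the list alone. After quantile normalization the medians were 0.23, 0.23 and 0.15, in that order, and that of glycolysis and hypoxia was 0.18 with PBS replicate 3 left out as well. No member of these lists passed over all genes. The array means of oxidative phosphorylation overlapped, with 9.036 in PBS replicate 1 and 9.026 in G-CSF replicates 1 and 3. Those of antioxidant genes overlapped too, with 8.414 in PBS replicate 1 and 8.374 and 8.354 in G-CSF replicates 1 and 3. The exact permutation p was 0.0857 for each of these 2 lists and 0.0286 for glycolysis and hypoxia. The antioxidant median was 0.13 without PBS replicate 3, and the call ended with the neutrophil covariate (adjusted p = 0.0784, median 0.25) and with quantile normalization and PBS replicate 3 left out (adjusted p = 0.0553, median 0.13). Cox5a, a subunit of cytochrome oxidase, had a log2 fold change of 0.93 ± 0.22 SE, the glycolytic gene Pgk1 0.69 ± 0.16 SE and the microsomal transferase Mgst1 1.93 ± 0.32 SE (adjusted p = 0.0612).

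Other lists called higher by camera had medians between 0.11 and 0.42. Among random lists of like intensity, multipotent and lymphoid-primed progenitor genes lay at percentile 99.98 and adhesion, homing and migration at 88.7. The lists called higher in the paragraphs above lay at 94.7 or more, apart from NF-kB targets at 72.36. Multipotent and lymphoid-primed progenitor genes had 0.42 (camera adjusted p = 5.77e-05, and with an estimated correlation adjusted p = 0.104), with 2 of 24 higher when adjusted over the list alone. The 1 member past the threshold over all genes was Wfdc17, while Dntt, the terminal transferase of lymphoid progenitors, had 2.12 ± 0.75 SE (adjusted p = 0.459). Dntt was 5.675, 5.339, 7.969 and 9.053 in G-CSF replicates 1 to 4, against 4.195 to 6.164 in the PBS arrays, so the groups overlapped. Adhesion, homing and migration had 0.21 (camera adjusted p = 3.81e-05, and with an estimated correlation adjusted p = 0.225), with 2 of 39 higher when adjusted over the list alone and 0 over all genes. The adhesion median was 0.07 without PBS replicate 3, 0.10 with array weights, 0.32 without PBS replicate 2 and 0.36 with the neutrophil covariate, and the call ended in the brighter genes (adjusted p = 0.0978, median 0.21) and with quantile normalization and PBS replicate 3 left out (adjusted p = 0.141, median 0.03). Selplg, the ligand of selectins, had 1.22 ± 0.31 SE.

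TGF-beta and BMP signalling had a median of 0.14 (camera adjusted p = 0.0231, and with an estimated correlation adjusted p = 0.151), where 1 of 29, Tgfbi, rose over all genes and when adjusted over the list alone. MYC targets and ribosome biogenesis had 0.19 (camera adjusted p = 0.008, and with an estimated correlation adjusted p = 0.56). The unfolded protein response had 0.11 (camera adjusted p = 0.0133, and with an estimated correlation adjusted p = 0.237), and ribosomal proteins, a sign of RNA quality, had 0.11 (camera adjusted p = 0.00525, and with an estimated correlation adjusted p = 0.151). No member of these last 3 lists passed over all genes or when adjusted over the list alone. Among random lists of like intensity, TGF-beta and BMP signalling lay at percentile 82.23 and MYC targets at 67.53. The unfolded protein response lay at 39.12 and ribosomal proteins at 17.89, so these 2 lists rose less than most such random lists. After quantile normalization the camera adjusted p was 0.217 for TGF-beta and BMP signalling, 0.886 for MYC targets, 0.545 for the unfolded protein response and 0.987 for ribosomal proteins, and the medians were then 0.03, 0.05, -0.08 and -0.05. Without PBS replicate 3 it was 0.177 for TGF-beta and BMP signalling (median 0.09), 0.493 for MYC targets (median 0.05) and 0.177 for the unfolded protein response (median 0.07). In the brighter genes none of these 4 lists passed, with adjusted p = 0.0978, 0.902, 0.858 and 0.805 in the order above, nor with quantile normalization and PBS replicate 3 left out (adjusted p = 0.462, 0.43, 0.678 and 0.802). Their medians were 0.27, 0.19, 0.11 and 0.11 in the brighter genes, and 0.02, -0.03, -0.01 and -0.02 with quantile normalization and PBS replicate 3 left out. With array weights the adjusted p was 0.104, 0.173 and 0.102 for the first 3 (medians 0.11, 0.08 and 0.12), and with the neutrophil covariate it was 0.59, 0.49 and 0.157 for the last 3 (medians 0.11, 0.07 and 0.10). Without PBS replicate 1 the MYC target median was 0.37 (adjusted p = 5.14e-05) and that of TGF-beta and BMP signalling 0.09, and the latter was 0.21 without PBS replicate 4 and 0.36 with the neutrophil covariate. The unfolded protein response median was 0.20 without PBS replicate 2. MYC targets had an adjusted p of 0.0757 without PBS replicate 4 (median 0.15), and the unfolded protein response had 0.0523 without G-CSF replicate 1 (median 0.09). The MYC target mean was highest in PBS replicate 1, at 8.534, against 8.292 to 8.475 after G-CSF (exact permutation p = 0.457).

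B cell markers were the 1 list below the other genes, with a median log2 fold change of -0.23 (camera adjusted p = 0.00525). The adjusted p = 0.289 with an estimated correlation, and 0 of 26 passed when adjusted over the list alone. The camera call ended with quantile normalization and PBS replicate 3 left out (adjusted p = 0.0604, median -0.16). It held without PBS replicate 3 alone (adjusted p = 0.0205, median -0.17). The B cell marker mean lay below the median of all genes on each array. It was 5.773 in PBS replicate 3, 5.351 to 5.534 in the other PBS arrays and 5.19 to 5.396 after G-CSF. Stem cell identity genes did not rank apart (camera adjusted p = 0.54), and their median of -0.0093 and mean of 0.04 differed in sign. Their median lay low among random lists of like intensity, at percentile 0.24, although their estimated inter-gene correlation was 0.35. They ranked higher without PBS replicate 4 (adjusted p = 0.0381) and with the neutrophil covariate (adjusted p = 0.0408), and lower with quantile normalization and PBS replicate 3 left out (adjusted p = 0.00354). Angpt1, the ligand of the Tie2 receptor, had a log2 fold change of -0.81 ± 0.19 SE and the junction protein Esam 0.89 ± 0.20 SE. The camera adjusted p was 0.986 for Wnt and Notch signalling, 0.178 for p53 targets and apoptosis, 0.986 for immediate-early and heat-shock genes, 0.229 for megakaryocyte and platelet markers, 0.178 for erythroid markers, 0.838 for mast cell, basophil and eosinophil markers, 0.218 for T cell and natural killer cell markers and 0.54 for endothelial and stromal markers. The median and mean differed in sign for immediate-early and heat-shock genes (0.0021 and -0.01), mast cell, basophil and eosinophil markers (-0.02 and 0.11) and endothelial and stromal markers (-0.05 and 0.07). Among random lists of like intensity, erythroid markers lay at percentile 0.02, immediate-early and heat-shock genes at 1.9 and megakaryocyte and platelet markers at 2.73. The T cell and natural killer cell list lay at 21.35, Wnt and Notch signalling at 33.8 and p53 targets and apoptosis at 73.67. Endothelial and stromal markers lay at 78.68 and mast cell, basophil and eosinophil markers at 88.92. Without PBS replicate 3, megakaryocyte and platelet markers and erythroid markers ranked lower (adjusted p = 0.0116 each), and erythroid markers also without G-CSF replicate 2 (adjusted p = 0.0286). In that order, their adjusted p was 0.0108 and 0.0108 with array weights, 0.0222 and 0.0169 in the brighter genes, and 0.00559 and 0.00705 with quantile normalization and PBS replicate 3 left out. With the neutrophil covariate it was 0.000117 and 2.22e-06, and T cell and natural killer cell markers then ranked lower too (adjusted p = 0.00102). Immediate-early and heat-shock genes ranked lower with quantile normalization and PBS replicate 3 left out (adjusted p = 0.00354). In all, 16 lists ranked higher and 1 lower with the preset correlation. The 1 list that passed with an estimated correlation was that of granulocyte-monocyte progenitor genes, and by fry 2 passed, that list and STAT3 and STAT5. Of the exact permutation tests of list means, 9 reached the smallest possible p of 0.0286, which is 0.0889 after adjustment over the 28 lists.

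**Figure D4:**
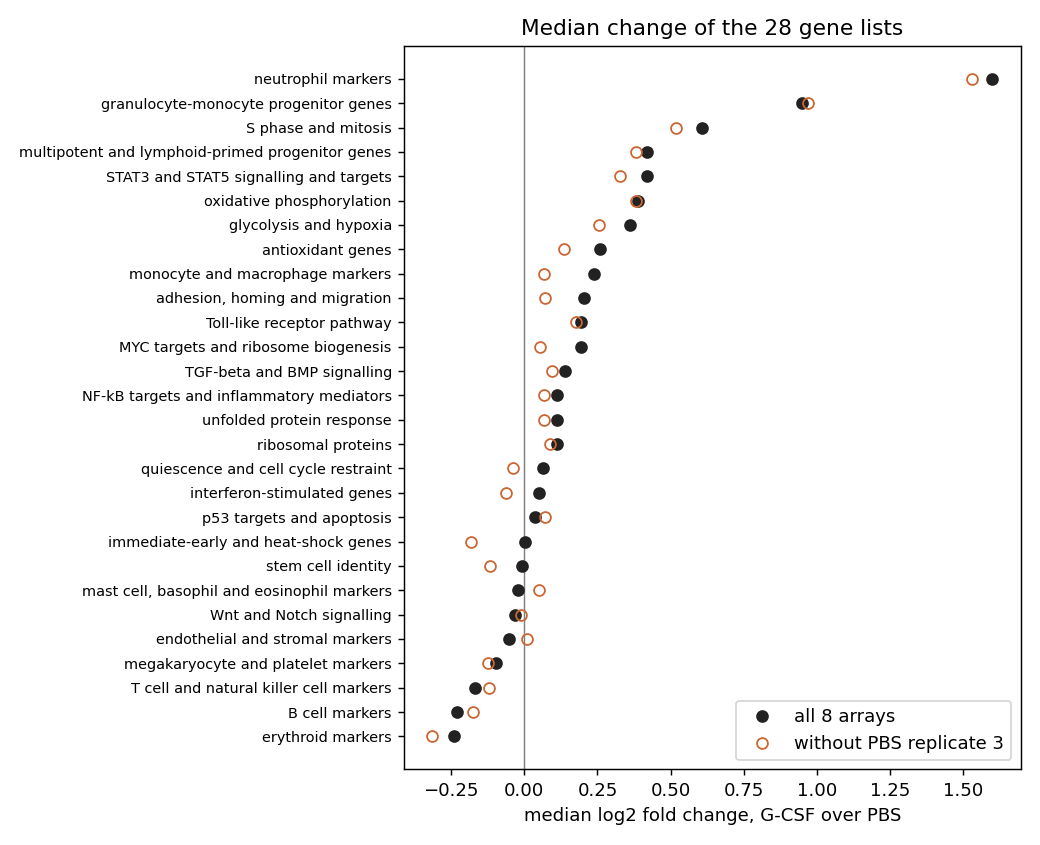
Median log2 fold change of G-CSF over PBS (horizontal axis) of the 28 gene lists, with all 8 arrays as filled circles and without PBS replicate 3 as open circles. Neutrophil markers are highest, at 1.60 with all arrays and 1.53 without PBS replicate 3.

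Genes of the surface proteins used in the sort did not pass the threshold. Kit had a log2 fold change of -0.35 ± 0.17 SE (adjusted p = 0.552), Slamf1, which encodes CD150, 0.16 ± 0.31 SE, Cd48 0.64 ± 0.36 SE and Itga2b, which encodes CD41, 0.10 ± 0.21 SE. Cd48, whose protein the sort selects against, was 7.306, 7.236, 7.846 and 8.953 in G-CSF replicates 1 to 4. It was 6.656 to 7.571 in the PBS arrays, so the groups overlapped but G-CSF replicate 4 was highest. The values of Slamf1 and Itga2b were negative without PBS replicate 3, at -0.07 and -0.01. Cxcr4, the receptor that retains stem cells in marrow, had 0.42 ± 0.31 SE (adjusted p = 0.627), and 0.066 without PBS replicate 3.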

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

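The count over other splits of the arrays was planned before its result was seen, and the other tests in this part were chosen after the values had been seen. Of 314 groups of 4 values examined, 17 held an array far from the rest, where chance alone gives about 5% of groups. The number flagged was thus close to what chance gives. PBS replicate 3 was the array apart in 9 of the 17.

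PBS replicate 3 stood apart in its interquartile range, with a gap of 0.926 of the group's range, and in its mean correlation with the other arrays, with 0.906. A narrower signal range alone was tested by quantile normalization, after which its mean correlation was still 0.898, against 0.953 or more for the others. A G-CSF sample under a PBS label was tested with the 26 genes called from the other 7 arrays, and PBS replicate 3 lay nearer the PBS mean at 22 of them, which argues against that. Poorer RNA or amplification stays open, since scanner files were not used here, and no biological explanation was tested.

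The 19 genes higher after G-CSF were compared with the 35 splits of the arrays into 4 and 4. Of these 1 gave as many genes, the real one, while the highest of the others gave 2. This argues against chance without excluding it, since 0.0286 is the smallest permutation p that 35 splits allow. The other splits also mix G-CSF with PBS arrays in each group. Granulocyte RNA as the whole cause was tested with the granulocyte signal as a covariate, measured in 4 ways, and the 95% interval stayed above 0 for 16 or more of the 19 genes under each, on genes selected for their difference. With the marker mean as the covariate 0 genes passed after adjustment (limma, 872 at an unadjusted p under 0.05), where the median SE was 1.74 times as large and the median retained share of the fold change was 0.974, ranging from 0.482 to 1.38. Socs3 went from 1.36 ± 0.18 SE to 1.64 ± 0.31 SE, whereas Lipg went from 2.83 ± 0.41 SE to 1.36 ± 0.48 SE. The intervals and retained shares argue against granulocyte RNA as the whole cause for 16 or more of the 19 genes. They do not exclude it, since the genes were selected for their difference and 0 passed after adjustment. Granulocyte RNA as part of the change in genes such as Lipg and a response of the sorted cells stay open.

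None of the 24 neutrophil markers is in another list, and 19 lay above the median of all genes in the PBS mean. Granulocytes present in differing amounts would raise the markers in proportion, and the lowest correlation across genes between 2 G-CSF arrays of their linear increases was 0.879, which is consistent with this. On the log2 scale it was 0.694, genes are not independent replicates, and a program switched on to differing degrees in the sorted cells would give the same. The lineage gate may remove granulocytes, but the labels do not list its markers, and among the most abundant S100a8 had 12.02 after PBS and 12.95 after G-CSF. A response of equal size in every treated pool cannot be told apart, since the SD over the G-CSF arrays was 2.75 times that over the PBS arrays and its 95% interval, from 0.70 to 10.8, includes 1, although the summed linear increases were 34920, 34260, 5848 and 10510 and the SD of 0.909 over the G-CSF arrays was above the median of 0.0922 and the highest of 0.371 of the other 27 lists.

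Other values far from their group, as the gap over the group's range, were as follows. In PBS replicate 3 they were Csf2rb (0.905), Slc19a1 (0.927), Ifitm2 (0.860), Notch4 (0.861), Rpl8 (0.850), Ms4a6c (0.851) and the mean of NF-kB targets (0.906). In PBS replicate 1 they were Hes1 (0.865) and the mean of oxidative phosphorylation (0.877), and in PBS replicate 4 Pdgfrb (0.853). In G-CSF replicate 4 they were Tex38 (0.988), Nr4a2 (0.856), Cct5 (0.864) and the mean of glycolysis and hypoxia (0.854), and in G-CSF replicate 2 Slc4a1 (0.956).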

How the results depend on the processing

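The covariate and the joint use of quantile normalization with PBS replicate 3 left out were chosen after the data had been seen. The 15 named genes past the threshold kept a positive fold change in each of their 254 alternative values. Their groups did not overlap, so leaving out or weighting arrays could not have changed the sign. The number of genes changed, 19 as designed, was 40 with array weights (37 higher, 3 lower), 7 with quantile normalization (7 higher), 52 at an adjusted p under 0.10 (52 higher), 0 with all probe sets (0 higher) and 0 with the covariate (0 higher). With all probe sets the prior degrees of freedom were 2.65 in place of 5.05, and the median SD was 0.487 for probe sets with several symbols or none and 0.321 for those with 1 symbol. All 21789 probe sets with 1 symbol gave 21. With quantile normalization and PBS replicate 3 left out there was 1 lower gene among 16. Leaving out each array in turn gave 3 to 31 changed genes, 3 to 30 higher and 0 to 2 lower, and 11 to 17 lists higher and 1 to 3 lower.

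The replicate block gave 23 genes, all higher, of which 15 were among the 19, and 16 and 1 lists. Same-numbered samples did not deviate together, with correlations of -0.025, 0.056, 0.062 and 0.14, and only PBS replicate 4 correlated best with its own number, so the numbers are not taken to pair samples.

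Lists higher, 16 as designed, were 8 among the brighter genes by mean, 10 with quantile normalization, 8 with quantile normalization and PBS replicate 3 left out, 10 with the covariate, 1 with an estimated correlation and 2 by fry. Lists lower, 1 as designed, were 3 with array weights, 3 among the brighter genes, 5 with quantile normalization and PBS replicate 3 left out, 5 with the covariate, 0 with an estimated correlation and 0 by fry. The sort markers stayed at 0 under each alternative.

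Several values reversed. Slamf1 was -0.036 with array weights, between -0.065 and 0.40 with 1 array left out (-0.065 without PBS replicate 3), -0.14 with quantile normalization and PBS replicate 3 left out and -0.63 with the covariate. Itga2b was -0.087 with quantile normalization, between -0.0089 and 0.21 with 1 array left out (-0.0089 without PBS replicate 3), -0.089 with both and -0.39 with the covariate. Cxcr4 was -0.047 with both. The ribosomal protein median was -0.048 with quantile normalization and -0.017 with both, and that of MYC targets and ribosome biogenesis was -0.028 with both. With the covariate, Cd14 was -0.40, Il1b -0.24, Itgb2 -0.16, Cct3 -0.025, Ctss -0.25, Alas2 0.010, Cldn13 0.44, Slc4a1 0.15, Alox5 -0.95, and Cd52 -0.060, and the log2 fold change of Tlr2 was -0.00544. Under it the neutrophil markers, the source of the covariate, had a median of 0.056 and ranked lower without passing, and the monocyte and macrophage markers ranked lower and passed (adjusted p = 0.000485, median -0.43). The cause was not tested. Without detection calls, the signal over background that limits dim genes is unknown.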

Other observations

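At adjusted p values between 0.05 and 0.10, 33 further genes were higher and 0 lower. They were read after their values were seen and did not pass the threshold. Among them were the C-type lectin Clec5a with a log2 fold change of 2.31 ± 0.37 SE, the Src-family kinase Fgr with 1.65 ± 0.27 SE, the calcium-binding proteins S100a6 with 2.14 ± 0.38 SE and S100a4 with 1.17 ± 0.21 SE, and Csf2rb2, the mouse paralog of Csf2rb, with 1.58 ± 0.27 SE. Probes of these paralogs can share sequence, so their values are not independent. The mitotic genes Cdca3 (1.01 ± 0.17 SE) and Sgo1 (0.99 ± 0.18 SE), which are in no list used here, were higher as well.

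Without PBS replicate 3, 26 genes passed, 16 of them among the 19. Those gained included Csf3r (1.46 ± 0.16 SE) and the myeloid transcription factor Spi1 (1.07 ± 0.15 SE). Lrg1, Lipg and AA467197 were lost, with adjusted p = 0.103, 0.0904 and 0.0881. The adjusted p ran from 0.0214 to 0.979 over 17 alternatives for Lrg1 and from 0.000388 to 0.979 over 16 for Lipg. The list medians without that array were -0.12 for megakaryocyte and platelet markers and -0.31 for erythroid markers.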
